A study of Bos taurus with 29 samples.

How the data were processed

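RNA was sequenced from bovine endometrial explants and from bovine corpus luteum samples, and the labels give both tissues as polyA RNA from a slaughterhouse source. Per the labels, the explants were cultured without an embryo (EE), with a single day 7 embryo produced in vivo (EE-AI) or with a single day 7 embryo produced in vitro (EE-IVF). The corpus luteum samples carry the labels NC, CM_EE, CM_EE_AI and CM_EE_IVF, written here as CL-NC, CL-CM-EE, CL-CM-EE-AI and CL-CM-EE-IVF. NC was taken as the control, and CM was read as medium conditioned by the explants, which the labels do not spell out. For both tissues the labels name a column kit for total RNA followed by DNase treatment. A stranded mRNA kit and a paired-end run are named for the endometrial explants, and the sentence that names them is repeated unchanged in the corpus luteum labels, so the kit of the corpus luteum libraries is not given in the sources used here.

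The authors deposited a table of whole read counts per gene for each tissue and a table of FPKM for the endometrium. The deposited corpus luteum values were whole counts in all 12 columns, so none held fractional expected counts. The submitters' processing notes name Trim Galore, cutadapt, STAR, featureCounts and DESeq2. Their versions, the genome build and the annotation are not given in the sources used here. The deposited FPKM values equalled the endometrial count divided by a fixed gene length and by the library total, to within 1 percent across libraries for all 13406 genes compared, so they carry no normalization beyond these. The endometrial table names 18180 genes by Ensembl ID and the corpus luteum table names 19112 genes, of which 17386 (91.0%) match a current symbol of the reference. The files used here do not pair the Ensembl IDs with symbols, so gene lists were tested in the corpus luteum alone and at most 2 IDs per direction are printed for the endometrium. The lowest sum of a corpus luteum gene over the 12 libraries was 36 counts, so low genes had been removed from that table, whereas the endometrial table holds genes at 0.

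The 9 endometrial columns match the 9 samples of the labels. The corpus luteum labels list 20 samples with the numbers R2, R4 and R5, of which R4 and R5 come with a pair of sample titles per group, while the table has 1 column per group and number. Each column was used as 1 library, giving 12 libraries, and how the title pairs were joined is not given in the sources used here. The title prefix of the R2 samples differs from those of R4 and R5, so R2 cannot be told apart from another sequencing run. Of the 21 pairs of libraries within a group, 0 were identical.

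Genes were kept with filterByExpr by group, which left 15077 endometrial and 18939 corpus luteum genes, and libraries were scaled by TMM. All groups of a tissue entered 1 model, edgeR quasi-likelihood with an F test, and p-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05 and no fold threshold. The 3 endometrial and 6 corpus luteum comparisons cover every pair of groups within a tissue. CPM are TMM-normalised counts scaled to a common library total, given as mean ± SD over 3 libraries, and intervals of log2 fold changes are 95% intervals of the edgeR fit. Gene lists were tested two-sided with limma camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, and again with a correlation estimated per list. Shares of counts were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1. The comparisons, tests, gene lists and the rule for naming genes were chosen before the data were examined. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

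By the naming rule, a comparison names up to 8 genes per direction with a symbol, past the threshold, at a mean of at least 1 CPM in either group and with groups that do not overlap. Where fewer than 4 genes passed, the 4 genes with a symbol and the lowest p were taken as values. Up to 4 members with the lowest p came from each list past its threshold, and up to 3 from the interferon, steroidogenesis, luteolysis, prostaglandin and vesicle lists in any case. Genes named outside this rule were chosen after their values were seen.

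The 30 lists, with the number of members tested, were interferon-stimulated genes (36), antigen presentation (17), inflammation and NF-kB targets (21), prostaglandin synthesis and signalling (18), progesterone, oestrogen and oxytocin response (17), uterine receptivity and histotroph (28), extracellular vesicle biogenesis (35), luteal steroidogenesis (22), cholesterol synthesis (22), luteolysis-associated genes (27), apoptosis and survival (22), angiogenic ligands and receptors (24), extracellular matrix and remodelling (27), hypoxia and glycolysis (27), heat shock and unfolded protein response (23), antioxidant and metal response (21), cell cycle (28), nuclear-encoded oxidative phosphorylation (26) and mitochondrially encoded transcripts (13). The marker lists were epithelium (9), ciliated cells (12), fibroblast and stroma (10), smooth muscle and pericyte (12), endothelium (14), macrophage and granulocyte (13), T and NK cells (14), B and plasma cells (7), erythroid cells and platelets (7), embryo and trophectoderm (6) and follicle cells (6). Some genes stand in more than 1 list, among them PTGFR, CYP19A1 and FGF2.

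The alternatives tried were DESeq2, median-of-ratios scaling, no filter, an adjusted p under 0.10, a log2 fold of at least 1, only the 2 groups compared in the fit, leaving out each library in turn, a block for the R number, ranks in camera, surrogate variables and limma on log2(FPKM + 1) for the endometrium. A robust fit, a fit without mitochondrial, ribosomal and 7SL RNA, a block for clusters of explant libraries, 1 and 3 surrogate variables, leaving out libraries or using median-of-ratios scaling in the list tests, and the R block with an estimated correlation were added after seeing the data.

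The tests were run on simulated data: negative binomial counts drawn from each gene's mean and dispersion at the observed library totals, with 67 genes changed 2-fold, 67 changed 4-fold and 66 changed 8-fold in 1 group. The changed genes were drawn only from those above a minimum mean CPM, so the recovery does not cover the lowest genes tested. The simulated libraries also held no relation between replicate numbers. In the 3 endometrial comparisons, edgeR recovered between 28.4% and 37.3% of genes changed 2-fold, between 89.6% and 92.5% of those changed 4-fold and between 93.9% and 97.0% of those changed 8-fold. In the 6 corpus luteum comparisons it recovered between 0% and 4.48% at 2-fold, between 38.8% and 59.7% at 4-fold and between 87.9% and 90.9% at 8-fold. It made between 2 and 11 false calls per comparison, and DESeq2, run on EE-AI against EE and CL-CM-EE against CL-NC, made 40 and 43. A simulated shift of 1 list was called by camera for that list and for 0 of the other lists, but the simulated genes were independent of one another, so this does not test false calls among correlated genes.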

Results

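Gene expression was measured by RNA sequencing in endometrial explants and in corpus luteum, the ovarian gland that secretes progesterone. The endometrium had 3 groups of 3 libraries: explants alone (EE), explants with an in vivo embryo (EE-AI) and explants with an in vitro embryo (EE-IVF), each embryo being at day 7. The corpus luteum had 4 groups of 3 libraries, CL-NC, CL-CM-EE, CL-CM-EE-AI and CL-CM-EE-IVF, and each group held 1 library with each of the numbers R2, R4 and R5. The labels do not say what the R numbers mark or whether the replicates are separate animals, so every p-value measures only the spread between these samples. Unless a block is named, the tests and the intervals of log2 fold changes model neither the R numbers nor the explant clusters of the endometrium.

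The endometrial libraries held between 6067951 and 8083238 counts, and the corpus luteum libraries held between 16536797 and 25747637 counts. Mitochondrial transcripts, mitochondrial ribosomal RNA among them, took between 44.4% and 64.0% of the corpus luteum counts. Ribosomal RNA, mitochondrial and nuclear together, took between 13.8% and 20.9%, so the shares overlap. Mitochondrial ribosomal RNA took between 11% and 18.2%, and nuclear ribosomal RNA between 1.98% and 4.59%. The ribosomal share of both kinds together was 19.6% ± 0.956 (SD, n = 3) in CL-CM-EE and 16.7% ± 1.97 in CL-NC, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. The mitochondrial share was 52.7% ± 7.3 in CL-NC, 54.1% ± 9.14 in CL-CM-EE, 52.4% ± 4.45 in CL-CM-EE-AI and 50.0% ± 4.52 in CL-CM-EE-IVF, with exact permutation p-values against CL-NC between 0.7 and 0.9. The biological coefficient of variation between libraries of a group was 0.271 in the endometrium and 0.519 in the corpus luteum. The median standard error of a log2 fold change was 0.247 in EE-AI against EE and 0.501 in CL-CM-EE-AI against CL-NC.

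The comparison of EE-AI with EE asks how explants differed after culture with an in vivo embryo. ENSBTAG00000012335 was at 13.8 ± 4.03 CPM in EE-AI and 6.33 ± 1.32 CPM in EE (SD, n = 3), a log2 fold change of 1.12 with a 95% interval from 0.53 to 1.71. ENSBTAG00000005280 was at 21.4 ± 4.99 CPM in EE-AI and 47.4 ± 9.84 CPM in EE, a log2 fold change of -1.15 with an interval from -1.65 to -0.64. Both were named as the lowest p in their direction, and neither passed the threshold. By edgeR, 0 of 15077 genes passed, 270 had an unadjusted p under 0.05 (94 higher and 176 lower in EE-AI), and DESeq2 called 0 with a lowest adjusted p of 0.079. With 3 surrogate variables in the model, a setting chosen after seeing the data, 12 genes passed.

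The comparison of EE-IVF with EE asks the same of an in vitro embryo. ENSBTAG00000002138 was at 0.942 ± 0.432 CPM in EE-IVF and 3.08 ± 0.684 CPM in EE (SD, n = 3), a log2 fold change of -1.68 with a 95% interval from -2.66 to -0.71. The gene with the lowest p among those higher in EE-IVF, whose ID is left out, was at 3.15 ± 1.10 and 0.455 ± 0.270 CPM, a log2 fold change of 2.76 with an interval from 1.04 to 4.47. Neither passed the threshold. With edgeR, 0 of 15077 genes passed, 56 had an unadjusted p under 0.05 (28 higher and 28 lower), and DESeq2 called 0 with a lowest adjusted p of 1. Without EE-IVF replicate 2, 1 gene passed: ENSBTAG00000052217, with an edgeR adjusted p of 0.0366. Its counts were 383, 0 and 240 in EE-IVF replicates 1, 2 and 3, and 1, 0 and 0 in EE. With all libraries this gene did not pass the filter on low counts, and it was named after its values were seen.

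The comparison of EE-IVF with EE-AI asks whether the origin of the embryo made a difference. ENSBTAG00000005280 was at 46.9 ± 6.78 CPM in EE-IVF and 21.4 ± 4.99 CPM in EE-AI (SD, n = 3), a log2 fold change of 1.13 with a 95% interval from 0.63 to 1.64. ENSBTAG00000002138 was at 0.942 ± 0.432 CPM in EE-IVF and 2.89 ± 0.807 CPM in EE-AI, a log2 fold change of -1.58 with an interval from -2.56 to -0.61. Neither passed the threshold. The edgeR test called 0 of 15077 genes, 219 had an unadjusted p under 0.05 (157 higher and 62 lower in EE-IVF), and DESeq2 called 0 with a lowest adjusted p of 0.112. Without EE-IVF replicate 2, 1 gene passed, ENSBTAG00000052217, with an edgeR adjusted p of 0.0304, and its counts were 0, 0 and 0 in EE-AI and 383, 0 and 240 in EE-IVF.

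Across the explants, libraries with the same replicate number resembled one another whatever their group. After centring on the group means, the correlations across genes lay between 0.416 and 0.738 for the 9 pairs within clusters 1, 2 and 3, each of which held 1 library of each group. They lay between -0.545 and 0.0421 for the 18 pairs from different clusters and groups, and genes are not independent replicates. Centring makes the deviations of a group sum to 0, so positive values within clusters bring negative ones between them, which are not separate evidence. The numbers in the sample titles step by 6 from EE to EE-AI and by 6 from EE-AI to EE-IVF within a cluster, and the labels do not say that they share a source. The main tests do not pair the clusters, although all correlations within them were over 0.1, the bound asked of the R numbers in the corpus luteum. Those tests leave this relation in the spread within groups. The endometrial intervals and gene p-values printed above come from them and include that spread. With the clusters as a block, chosen after seeing the data, edgeR called 0 genes in each of the 3 comparisons. The number with an unadjusted p under 0.05 was then 1243 in EE-AI against EE, 282 in EE-IVF against EE and 1243 in EE-IVF against EE-AI. For comparison, 5% of the genes tested is 754 in the endometrium and 947 in the corpus luteum, a number that holds for libraries with no shared structure. The counts without a block were below it in all 9 comparisons, and those with the cluster block were above it in 2 of 3.

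**Figure D1:**
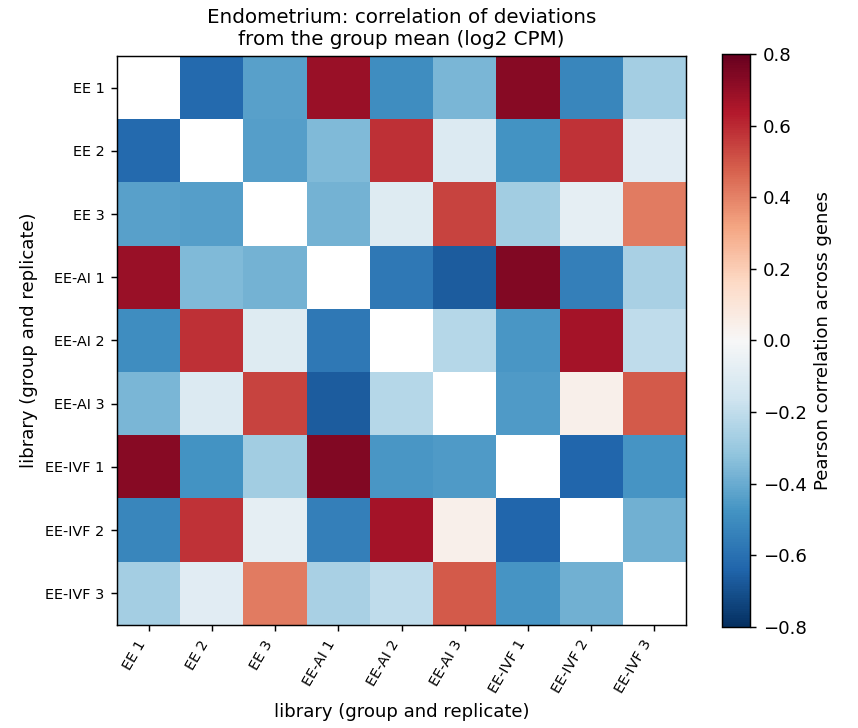
Pearson correlation across genes between the 9 endometrial libraries, named by group and replicate on both axes, of log2 CPM after subtracting the group mean; colour gives the correlation and the diagonal is left blank. The 9 pairs of different groups with the same replicate number are between 0.416 and 0.738.

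The comparison of CL-CM-EE with CL-NC asks how corpus luteum with medium of explants alone differed from its control. Of the luteal steroidogenesis list, STARD3, which carries cholesterol in late endosomes, was at 7.47 ± 0.550 CPM in CL-CM-EE and 5.79 ± 1.88 CPM in CL-NC (SD, n = 3), a log2 fold change of 0.37 with a 95% interval from -0.42 to 1.15, which became 0.24 without CL-NC R2 and 0.61 without CL-NC R5. PTGFR, the prostaglandin F receptor and a member of the prostaglandin and the luteolysis lists, was at 201 ± 154 and 124 ± 23.9 CPM, a log2 fold change of 0.70 with an interval from -0.82 to 2.21. It turned to -0.14 without CL-CM-EE R4. Of the interferon-stimulated genes, LGALS9 was at 99.8 ± 60.9 and 50.1 ± 13.7 CPM, with an interval of its log2 fold change from -0.14 to 2.13, and the value of 0.99 became 0.38 without CL-CM-EE R5. Of the vesicle list, YKT6, a membrane fusion protein, was at 6.93 ± 2.66 and 9.17 ± 3.84 CPM, with an interval from -1.21 to 0.40, and the value of -0.41 became -0.02 without CL-NC R4 and -0.76 without CL-CM-EE R4.

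Of the 4 genes with the lowest p in CL-CM-EE against CL-NC, MYO15B was at 6.43 ± 4.83 CPM in CL-CM-EE and 0.429 ± 0.164 CPM in CL-NC (SD, n = 3), a log2 fold change of 3.89 with a 95% interval from 1.76 to 6.02. ANKRD63 reached 1030 CPM in CL-CM-EE R2 alone, and its log2 fold change of 10.5 became -1.10 without that library. ZNF200 reached 121 CPM in CL-CM-EE R4, and its log2 fold change of 4.33 became 0.23 without it. FABP6 reached 14.7 CPM in CL-CM-EE R5, and its log2 fold change of 4.23 became 1.51 without it. By edgeR, 0 of 18939 genes passed, 142 had an unadjusted p under 0.05 (80 higher and 62 lower), and DESeq2 called 0 with a lowest adjusted p of 0.138. Of the 30 lists, 0 passed by camera, with adjusted p between 0.201 and 0.965, and 0 members passed adjusted over the list alone. With the R number as a block, 4 lists passed with the preset correlation and 0 with an estimated one. Leaving out 1 library gave 5 lists without CL-NC R2, 4 without CL-NC R4, 1 without CL-NC R5, 6 without CL-CM-EE R2, 4 without CL-CM-EE R4 and 9 without CL-CM-EE R5.

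The comparison of CL-CM-EE-AI with CL-NC asks how corpus luteum differed with medium of explants that held an in vivo embryo. With the preset correlation, the lists of luteal steroidogenesis, cholesterol synthesis and oxidative phosphorylation were higher, and each lost its call with an estimated one (adjusted p = 0.982 with an estimated correlation for all 3). STAR, which brings cholesterol into mitochondria, was at 421 ± 489 CPM in CL-CM-EE-AI and 187 ± 25.1 CPM in CL-NC (SD, n = 3), and by number it was at 986 in R4, 140 in R2 and 138 in R5 of CL-CM-EE-AI. HSD3B1, which makes progesterone from pregnenolone, was at 1330 ± 1010 and 623 ± 158 CPM, a log2 fold change of 1.10 with a 95% interval from -0.03 to 2.23, which became 0.29 without CL-CM-EE-AI R4. NDUFV1, a subunit of respiratory complex I, was at 17.4 ± 7.51 and 10.5 ± 1.36 CPM, a log2 fold change of 0.74 with an interval from 0.03 to 1.45, which became 0.34 without that library. No gene passed on its own, and 7 of 30 lists passed by camera with the preset correlation, 5 higher and 2 lower.

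**Figure D2:**
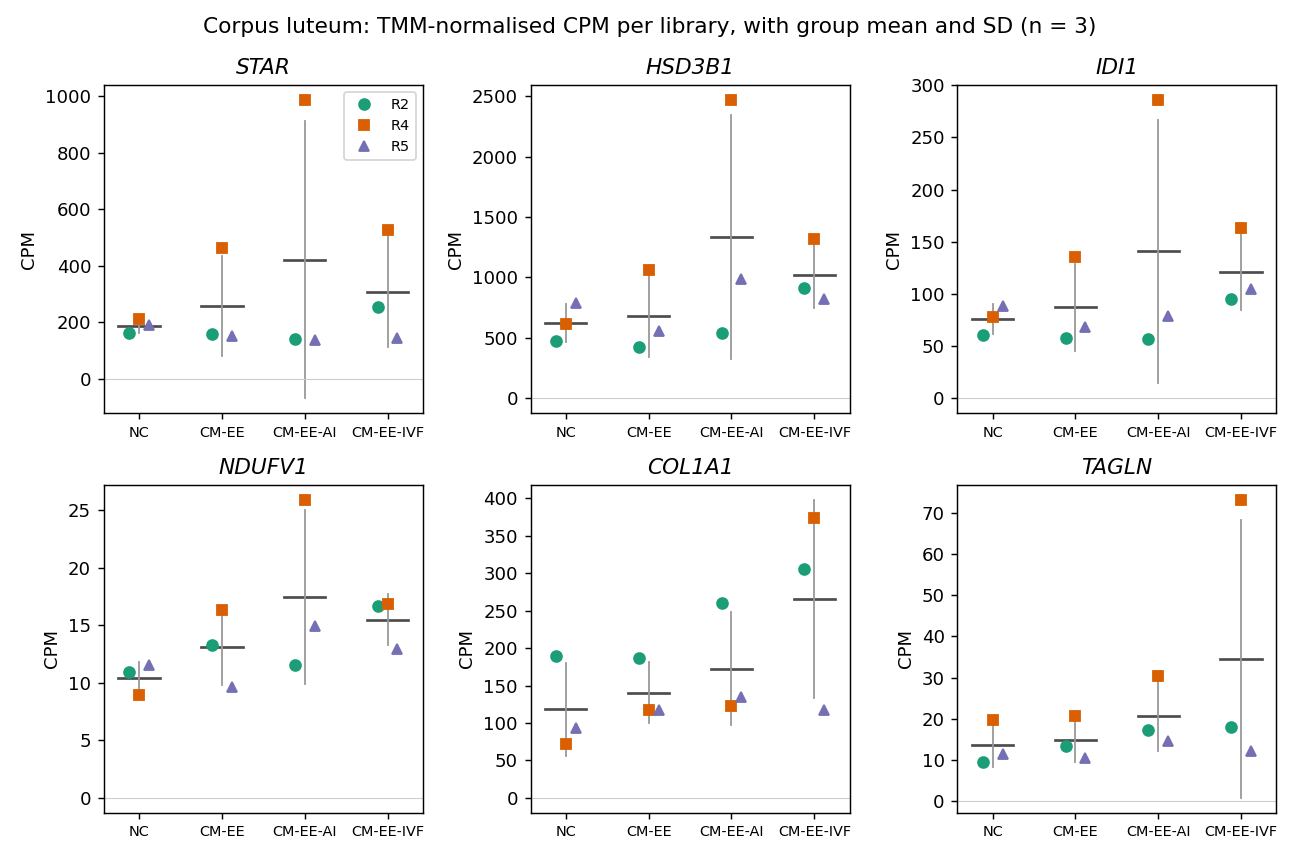
TMM-normalised CPM (vertical axis, linear) of 6 genes in the 12 corpus luteum libraries by group (horizontal axis); symbols mark the R number, horizontal lines the group mean and vertical lines the mean ± SD (n = 3), which reach below 0 where the SD exceeds the mean. STAR in CL-CM-EE-AI was at 986 CPM in R4 and at 140 and 138 CPM in R2 and R5.

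Luteal steroidogenesis was higher in CL-CM-EE-AI than in CL-NC, with 16 of 22 members above 0, a median log2 fold change of 0.59 and an adjusted p of 0.0122 (adjusted p = 0.982 with an estimated correlation). It was lost without CL-NC R2 (adjusted p = 0.321) and without CL-CM-EE-AI R4 (adjusted p = 0.793), and STAR went from a log2 fold change of 1.17 to -0.43 without the latter. MC2R, the corticotropin receptor in this list, went the other way at 0.206 ± 0.164 and 1.01 ± 0.379 CPM (SD, n = 3), with a 95% interval of its log2 fold change from -4.47 to -0.02. Cholesterol synthesis was higher in 22 of 22 members, with a median of 0.60 and an adjusted p of 0.0122 (adjusted p = 0.982 with an estimated correlation). Without CL-NC R2 its adjusted p was 0.863, and without CL-CM-EE-AI R4 the list was lower, with an adjusted p of 0.0363. All 22 members differed between R numbers with the highest mean in R4. Leaving out either library unbalances the R numbers, so these 2 fits do not show the effect of a single library alone. IDI1, an isomerase of the mevalonate pathway, was at 141 ± 126 and 75.7 ± 14.1 CPM, and its log2 fold change of 0.90 became -0.15 without CL-CM-EE-AI R4. Nuclear-encoded oxidative phosphorylation was higher in 26 of 26 members, with a median of 0.55 and an adjusted p of 3.29e-07 (adjusted p = 0.982 with an estimated correlation; 0.793 without CL-CM-EE-AI R4). Mitochondrially encoded transcripts did not pass in this comparison.

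Follicle cell markers were higher in CL-CM-EE-AI than in CL-NC in 6 of 6 members, with a median log2 fold change of 0.77 and an adjusted p of 0.0122 (adjusted p = 0.982 with an estimated correlation). FSHR, the follicle-stimulating hormone receptor, was at 23.3 ± 6.47 and 13.2 ± 3.20 CPM (SD, n = 3), and FOXL2, a granulosa cell transcription factor that also stands in the hormone response list, was at 5.17 ± 1.90 and 3.14 ± 0.516 CPM, a log2 fold change of 0.72 that became 0.38 without CL-CM-EE-AI R4. In both genes each library of CL-CM-EE-AI was above each library of CL-NC, which chance gives in 10% of genes for both directions together. The list was lost without CL-NC R2 (adjusted p = 0.155), without CL-NC R5 (0.104) and without CL-CM-EE-AI R4 (0.316). Fibroblast and stroma markers were higher in 8 of 10 members, with a median of 0.29 and an adjusted p of 0.0216 (adjusted p = 0.5 with an estimated correlation). They were lost without CL-NC R4 (0.0931), CL-NC R5 (0.143), CL-CM-EE-AI R2 (0.121) or CL-CM-EE-AI R5 (0.0681).

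Angiogenic ligands and receptors were lower in CL-CM-EE-AI than in CL-NC in 19 of 24 members, with a median log2 fold change of -0.21 and an adjusted p of 0.0356 (adjusted p = 0.982 with an estimated correlation). PDGFC, a growth factor of stromal cells, was at 182 ± 25.5 and 319 ± 165 CPM (SD, n = 3), a log2 fold change of -0.81 that became -0.33 without CL-NC R4. The list was lost without CL-NC R2 (adjusted p = 0.366), CL-NC R4 (0.104), CL-CM-EE-AI R4 (0.270) or CL-CM-EE-AI R5 (0.151). Endothelial markers were lower in 11 of 14 members, with a median of -0.21 and an adjusted p of 0.0455 (adjusted p = 0.982 with an estimated correlation). EMCN, an endothelial sialomucin, was at 151 ± 22.4 and 244 ± 117 CPM, a log2 fold change of -0.69 that became -0.28 without CL-NC R4. The list was lost without CL-NC R2 (0.366), CL-NC R5 (0.172) or CL-CM-EE-AI R5 (0.0667), and it turned higher without CL-CM-EE-AI R4 (0.930).

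Within R numbers, with 1 library per group and chosen after seeing the data, the differences between CL-CM-EE-AI and CL-NC were largest in R4 for 6 of these 7 lists. The median log2 CPM difference of luteal steroidogenesis was 1.09 in R4, 0.09 in R2 and 0.15 in R5, and that of cholesterol synthesis was 1.18 in R4, 0.02 in R2 and -0.12 in R5. Oxidative phosphorylation differed by 1.43 in R4, -0.08 in R2 and -0.17 in R5. Angiogenic genes differed by -0.40, -0.06 and -0.03 in R4, R2 and R5, and endothelial markers by -0.62, 0.01 and -0.22. Follicle cell markers were higher in each number, by 0.98 in R4, 0.51 in R2 and 0.61 in R5. Fibroblast markers differed by 0.25 in R4, -0.09 in R2 and 0.49 in R5.

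With edgeR, 0 of 18939 genes passed between CL-CM-EE-AI and CL-NC, 213 had an unadjusted p under 0.05 (109 higher and 104 lower), and DESeq2 called 0 with a lowest adjusted p of 0.419. The lowest p belonged to ULBP27 (log2 fold change 3.09, 95% interval from 1.33 to 4.85), TMPRSS2 (-1.90, from -2.99 to -0.81), TPPP2 (6.03, from 2.46 to 9.60) and PLA2G12B (-4.05, from -6.50 to -1.60). Without CL-CM-EE-AI R2 the value of TPPP2 was 1.05, and without CL-NC R4 that of PLA2G12B was -1.17. TMPRSS2 was at 1.77 ± 0.350 CPM in CL-CM-EE-AI and 6.62 ± 2.87 CPM in CL-NC (SD, n = 3), and TPPP2 was at 156 CPM in CL-CM-EE-AI R2, 0.170 in R4 and 3.39 in R5. The other 23 lists had adjusted p between 0.180 and 0.973, and 0 list members passed adjusted over the list alone. The number of lists past the threshold was 4 without CL-NC R5 and 4 without CL-CM-EE-AI R4.

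The comparison of CL-CM-EE-IVF with CL-NC asks the same of explants with an in vitro embryo. With the preset correlation, the lists of fibroblast, smooth muscle and macrophage markers, matrix, steroidogenesis, cholesterol synthesis and oxidative phosphorylation were higher. Of these 7, the fibroblast list also passed with an estimated correlation (adjusted p = 0.0345 with an estimated correlation), and the other 6 did not (adjusted p between 0.641 and 0.963 with an estimated correlation). COL1A1, a chain of type I collagen, was at 266 ± 132 CPM in CL-CM-EE-IVF and 118 ± 61.9 CPM in CL-NC (SD, n = 3), a log2 fold change of 1.17 with a 95% interval from 0.11 to 2.22. TAGLN, an actin-binding protein of smooth muscle, was at 34.5 ± 33.8 and 13.5 ± 5.40 CPM, a log2 fold change of 1.35 with an interval from 0.06 to 2.64, which became 0.15 without CL-CM-EE-IVF R4. CD163, a scavenger receptor of macrophages, was at 10.1 ± 6.70 and 3.72 ± 1.08 CPM, a log2 fold change of 1.45 with an interval from 0.52 to 2.37, which became 0.78 without that library. No gene passed on its own, and 7 of 30 lists passed by camera with the preset correlation, all 7 higher.

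Fibroblast and stroma markers were higher in CL-CM-EE-IVF than in CL-NC in 8 of 10 members, with a median log2 fold change of 0.59 and an adjusted p of 4.94e-05. This list passed with an estimated correlation (adjusted p = 0.0345 with an estimated correlation) and, with the preset correlation, whichever of the 6 libraries was left out. With the R number as a block it passed with the preset correlation and did not pass with an estimated one (adjusted p = 0.211 with an estimated correlation). PDGFRA, a receptor of stromal cells, was at 27.0 ± 4.99 and 14.1 ± 9.74 CPM (SD, n = 3) and LUM, the matrix proteoglycan lumican, at 124 ± 40.7 and 72.4 ± 22.2 CPM. The log2 fold change of PDGFRA was 0.93, or 0.49 without CL-NC R4 and 1.55 without CL-NC R2. Smooth muscle and pericyte markers were higher in 12 of 12 members, with a median of 0.64 and an adjusted p of 6.77e-05 (adjusted p = 0.641 with an estimated correlation; 0.3 without CL-CM-EE-IVF R4). ACTA2, smooth muscle actin, was at 221 CPM in R4, 51.2 in R2 and 33.3 in R5 of CL-CM-EE-IVF, and its log2 fold change of 1.21 became -0.06 without R4. Extracellular matrix and remodelling was higher in 18 of 27 members, with a median of 0.25 and an adjusted p of 0.00786 (adjusted p = 0.963 with an estimated correlation). It was lost without CL-NC R5 (0.607), CL-CM-EE-IVF R2 (0.826) or CL-CM-EE-IVF R4 (0.0637). Macrophage and granulocyte markers were higher in 11 of 13 members, with a median of 0.25 and an adjusted p of 0.0192 (adjusted p = 0.955 with an estimated correlation). They were lost without CL-NC R2 (0.0616), CL-NC R4 (0.0891) or CL-CM-EE-IVF R4 (0.496).

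Luteal steroidogenesis was higher in CL-CM-EE-IVF than in CL-NC in 16 of 22 members, with a median log2 fold change of 0.40 and an adjusted p of 0.0154 (adjusted p = 0.955 with an estimated correlation). It was lost without CL-NC R2 (0.318) or CL-CM-EE-IVF R4 (0.176). HSD3B1 was at 1020 ± 268 and 623 ± 158 CPM (SD, n = 3) and SCARB1, the receptor that takes up cholesterol from lipoproteins, at 401 ± 86.8 and 283 ± 11.9 CPM, with each library of CL-CM-EE-IVF above each of CL-NC. Cholesterol synthesis was higher in 22 of 22 members, with a median of 0.37 and an adjusted p of 0.000652 (adjusted p = 0.963 with an estimated correlation). It was lost without CL-NC R2 (0.572) or CL-CM-EE-IVF R4 (0.256). FDPS, farnesyl diphosphate synthase, was at 108 ± 25.8 and 68.3 ± 23.0 CPM. Oxidative phosphorylation was higher in 26 of 26 members, with a median of 0.36 and an adjusted p of 4.94e-05 (adjusted p = 0.963 with an estimated correlation; 0.0586 without CL-CM-EE-IVF R2).

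Within R numbers, the fibroblast and stroma difference between CL-CM-EE-IVF and CL-NC was 1.77 in R4, 0.37 in R2 and 0.42 in R5 as a median in log2 CPM. Smooth muscle markers differed by 1.28 in R4, 0.39 in R2 and 0.01 in R5, matrix genes by 0.63, 0.14 and -0.04, and macrophage markers by 0.94, -0.01 and -0.04. Steroidogenesis differed by 0.55 in R4, 0.64 in R2 and 0.15 in R5, cholesterol synthesis by 0.53, 0.67 and 0.00, and oxidative phosphorylation by 0.88, 0.23 and -0.17.

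**Figure D3:**
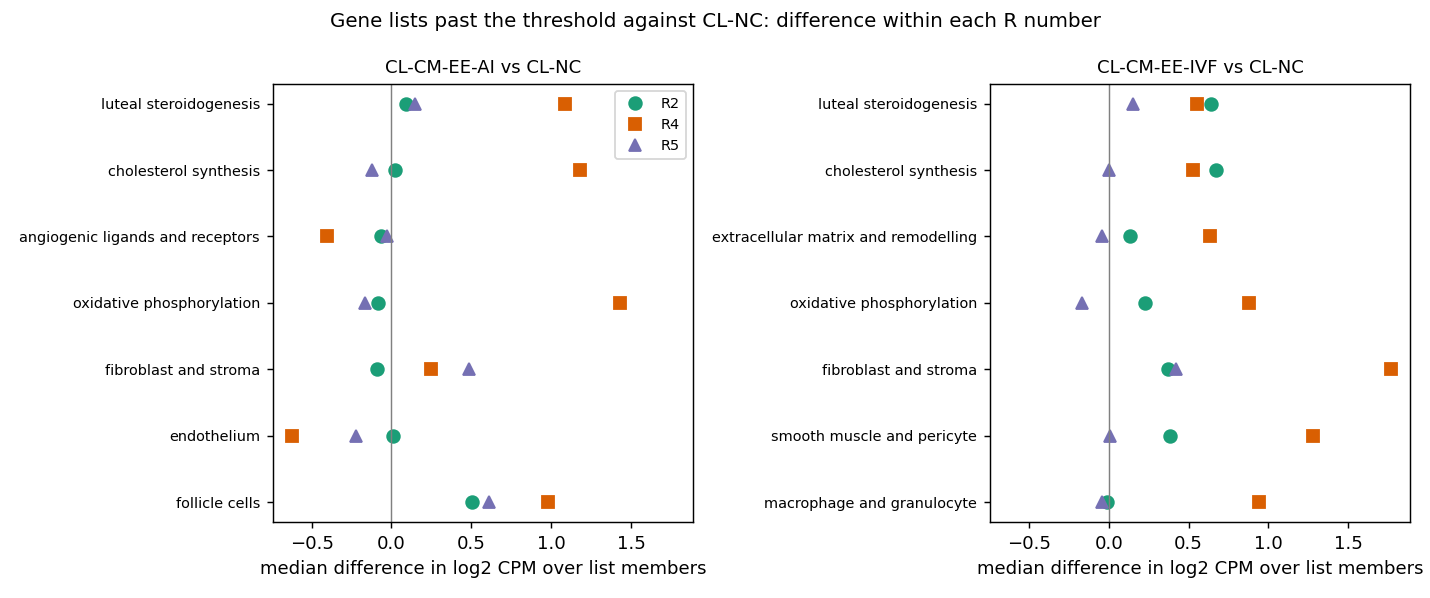
Median difference in log2 CPM over list members (horizontal axis) within each R number for the lists past the threshold (vertical axis), for CL-CM-EE-AI against CL-NC on the left and CL-CM-EE-IVF against CL-NC on the right; each symbol compares 1 library with 1 library. R4 gives 1.43 for oxidative phosphorylation on the left and 1.77 for fibroblast and stroma markers on the right.

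The edgeR test called 0 of 18939 genes between CL-CM-EE-IVF and CL-NC, 281 had an unadjusted p under 0.05 (108 higher and 173 lower), and DESeq2 called 0 with a lowest adjusted p of 0.631. The lowest p belonged to KLF15 and KCNQ5, which reached 953 CPM in R4 and 2060 CPM in R2 of CL-CM-EE-IVF, and to PLA2G12B (log2 fold change -4.25, 95% interval from -6.71 to -1.79) and CAPN12 (-2.77, from -4.38 to -1.16). The log2 fold change of KLF15 went from 8.44 to 0.90 without CL-CM-EE-IVF R4, that of KCNQ5 from 5.71 to 0.17 without CL-CM-EE-IVF R2 and that of PLA2G12B to -1.37 without CL-NC R4. The other 23 lists had adjusted p between 0.0800 and 0.916, and 0 list members passed adjusted over the list alone. The number of lists past the threshold was 12 without CL-NC R4, 2 without CL-CM-EE-IVF R4 and 12 without CL-CM-EE-IVF R5.

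The comparison of CL-CM-EE-AI with CL-CM-EE asks what an in vivo embryo added to the explant medium. With the preset correlation, the lists of cholesterol synthesis and oxidative phosphorylation were higher and that of endothelial markers was lower, and all 3 lost the call with an estimated one (adjusted p = 0.938 with an estimated correlation for each). Cholesterol synthesis was higher in 22 of 22 members, with a median log2 fold change of 0.58 and an adjusted p of 0.0119 (adjusted p = 0.938 with an estimated correlation). MVD, mevalonate decarboxylase, was at 26.0 ± 11 CPM in CL-CM-EE-AI and 16.7 ± 5.53 CPM in CL-CM-EE (SD, n = 3). Oxidative phosphorylation was higher in 26 of 26 members, with a median of 0.41 and an adjusted p of 0.000162 (adjusted p = 0.938 with an estimated correlation). NDUFS1, a subunit of complex I, was at 16.8 ± 6.56 and 10.3 ± 2.65 CPM. Endothelial markers were lower in 14 of 14 members, with a median of -0.26 and an adjusted p of 0.0122 (adjusted p = 0.938 with an estimated correlation). SOX18, an endothelial transcription factor, was at 5.12 ± 1.47 and 8.07 ± 4.08 CPM. The log2 fold change of SOX18 went from -0.65 to -0.16 without CL-CM-EE R2 and to -0.98 without CL-CM-EE-AI R2, and those of MVD and NDUFS1 from 0.64 to 0.35 and from 0.71 to 0.40 without CL-CM-EE-AI R4.

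Without CL-CM-EE-AI R4, cholesterol synthesis turned lower than in CL-CM-EE (adjusted p = 0.0425), oxidative phosphorylation turned lower (0.632) and endothelial markers did not pass (0.729). That comparison held R4 in CL-CM-EE alone. Without CL-CM-EE R2, cholesterol synthesis did not pass (0.858) and endothelial markers turned higher (0.889). Without CL-CM-EE R5, cholesterol synthesis (0.180) and oxidative phosphorylation (0.471) did not pass. Within R numbers the median log2 CPM difference was 0.71 in R4, 0.07 in R2 and 0.46 in R5 for cholesterol synthesis, 0.80, -0.10 and 0.34 for oxidative phosphorylation and -0.74, -0.44 and 0.21 for endothelial markers. By edgeR, 0 of 18939 genes passed, 242 had an unadjusted p under 0.05 (134 higher and 108 lower), and DESeq2 called 0 with a lowest adjusted p of 0.0709. The lowest p belonged to MYO15B (log2 fold change -4.02), TPPP2 (6.76, or 1.79 without CL-CM-EE-AI R2), ANKRD63 (-11, turning to 0.64 without CL-CM-EE R2) and TMPRSS2 (-1.83, 95% interval from -2.92 to -0.74). The other 27 lists had adjusted p between 0.0587 and 0.984, and 0 list members passed adjusted over the list alone. With the R number as a block 5 lists passed with the preset correlation and 0 with an estimated one. The number of lists past the threshold was 7 without CL-CM-EE R4, 8 without CL-CM-EE R5, 8 without CL-CM-EE-AI R2, 7 without CL-CM-EE-AI R4 and 5 without CL-CM-EE-AI R5.

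The comparison of CL-CM-EE-IVF with CL-CM-EE asks what an in vitro embryo added. With the preset correlation, the lists of fibroblast and smooth muscle markers, cholesterol synthesis and oxidative phosphorylation were higher, and all 4 lost the call with an estimated one (adjusted p between 0.0505 and 0.946 with an estimated correlation). Fibroblast and stroma markers were higher in 9 of 10 members, with a median log2 fold change of 0.71 and an adjusted p of 0.000275 (adjusted p = 0.0505 with an estimated correlation), and with the preset correlation they passed whichever of the 6 libraries was left out. PDGFRA was at 27.0 ± 4.99 CPM in CL-CM-EE-IVF and 12.7 ± 3.83 CPM in CL-CM-EE (SD, n = 3), a log2 fold change of 1.09 with a 95% interval from 0.02 to 2.15. MEIS1, a homeobox gene of stromal cells, was at 23.8 ± 2.89 and 16.1 ± 2.89 CPM, a log2 fold change of 0.56 with an interval from 0.02 to 1.10. In both genes each library of CL-CM-EE-IVF was above each of CL-CM-EE. Smooth muscle and pericyte markers were higher in 12 of 12 members, with a median of 0.80 and an adjusted p of 0.00076 (adjusted p = 0.722 with an estimated correlation; 0.701 without CL-CM-EE-IVF R4). MYLK, myosin light chain kinase, was at 88.7 ± 32.9 and 50.6 ± 12.9 CPM, with an interval of its log2 fold change from 0.05 to 1.57, and the value of 0.81 became 0.50 without CL-CM-EE-IVF R4. Cholesterol synthesis was higher in 22 of 22 members, with a median of 0.36 and an adjusted p of 0.00076 (adjusted p = 0.946 with an estimated correlation). Oxidative phosphorylation was higher in 24 of 26 members, with a median of 0.25 and an adjusted p of 0.00509 (adjusted p = 0.946 with an estimated correlation).

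Cholesterol synthesis in CL-CM-EE-IVF against CL-CM-EE did not pass without CL-CM-EE R2 (adjusted p = 0.479) or CL-CM-EE-IVF R4 (0.338), and oxidative phosphorylation did not pass without CL-CM-EE R5 (0.925), CL-CM-EE-IVF R2 (0.392) or CL-CM-EE-IVF R4 (0.397). Within R numbers the median log2 CPM difference was 0.97 in R4, 0.39 in R2 and 0.30 in R5 for fibroblast markers and 1.28, 0.16 and 0.41 for smooth muscle markers. It was 0.08, 0.74 and 0.58 for cholesterol synthesis and 0.12, 0.26 and 0.21 for oxidative phosphorylation. With edgeR, 0 of 18939 genes passed, 285 had an unadjusted p under 0.05 (119 higher and 166 lower), and DESeq2 called 0 with a lowest adjusted p of 0.172. The lowest p belonged to KLF15 (log2 fold change 8.58, or 1.05 without CL-CM-EE-IVF R4), SPATC1 (-4.50), ZNF200 (-4.66, or -0.55 without CL-CM-EE R4) and ANKRD63 (-10.5, or 1.13 without CL-CM-EE R2). The other 26 lists had adjusted p between 0.125 and 0.892, and 0 list members passed adjusted over the list alone. With the R number as a block 8 lists passed with the preset correlation and 0 with an estimated one. The number of lists past the threshold was 9 without CL-CM-EE R4, 10 without CL-CM-EE R5, 10 without CL-CM-EE-IVF R2 and 1 without CL-CM-EE-IVF R4.

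The comparison of CL-CM-EE-IVF with CL-CM-EE-AI asks whether the origin of the embryo mattered for the corpus luteum. Smooth muscle and pericyte markers were higher with the in vitro embryo in 11 of 12 members, with a median log2 fold change of 0.50 and an adjusted p of 0.00342 (adjusted p = 0.994 with an estimated correlation). ACTG2, an actin of smooth muscle, was at 12.5 ± 14.0 CPM in CL-CM-EE-IVF and 5.87 ± 2.92 CPM in CL-CM-EE-AI (SD, n = 3), and its log2 fold change of 1.10 became -0.40 without CL-CM-EE-IVF R4. Matrix and remodelling genes were higher in 18 of 27 members, with a median of 0.16 and an adjusted p of 0.0184 (adjusted p = 0.994 with an estimated correlation). COL1A1 was at 266 ± 132 and 173 ± 75.8 CPM, with a 95% interval of its log2 fold change from -0.42 to 1.67, and the value of 0.62 became 0.30 without CL-CM-EE-IVF R4 and 1.11 without CL-CM-EE-AI R2. CYP19A1, the enzyme that makes oestrogens, was at 2.26 ± 0.520 and 4.57 ± 0.820 CPM, with an interval from -2.28 to 0.25, and each library of CL-CM-EE-IVF was below each of CL-CM-EE-AI.

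The smooth muscle list in CL-CM-EE-IVF against CL-CM-EE-AI did not pass without CL-CM-EE-AI R2 (adjusted p = 0.143) and turned lower without CL-CM-EE-IVF R4 (0.751). The matrix list did not pass without CL-CM-EE-IVF R4 (0.167) and turned lower without CL-CM-EE-AI R5 (0.750) or CL-CM-EE-IVF R2 (0.728). Within R numbers the median log2 CPM difference of smooth muscle markers was 1.34 in R4, 0.10 in R2 and -0.16 in R5, and that of matrix genes was 0.25, 0.13 and 0.04. The edgeR test called 0 of 18939 genes, 127 had an unadjusted p under 0.05 (54 higher and 73 lower), and DESeq2 called 0 with a lowest adjusted p of 0.553. The lowest p belonged to TPPP2 (log2 fold change -6.24, or -1.26 without CL-CM-EE-AI R2), AGXT (8.63, or 1.42 without CL-CM-EE-IVF R2), KCNQ5 (5.76, or 0.22 without CL-CM-EE-IVF R2) and KLF15 (7.53, or -0.02 without CL-CM-EE-IVF R4). The other 28 lists had adjusted p between 0.0515 and 0.983, and 0 list members passed adjusted over the list alone. With the R number as a block 5 lists passed with the preset correlation and 0 with an estimated one. The number of lists past the threshold was 7 without CL-CM-EE-AI R2, 11 without CL-CM-EE-AI R4, 7 without CL-CM-EE-AI R5, 6 without CL-CM-EE-IVF R2, 0 without CL-CM-EE-IVF R4 and 9 without CL-CM-EE-IVF R5.

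Without a block for the R number, lists on embryo signalling did not pass in the 6 corpus luteum comparisons. With that block and the preset correlation more lists passed in some comparisons. The added lists are not named here, so those of this paragraph may be among them. The interferon-stimulated genes, the classical response to the embryonic signal of ruminants, had a lowest adjusted p of 0.424, in CL-CM-EE-IVF against CL-CM-EE. ISG15, a ubiquitin-like protein of this response, was at 20.7 ± 1.33 CPM in CL-NC, 28.1 ± 12.3 in CL-CM-EE, 28.2 ± 11.5 in CL-CM-EE-AI and 26.3 ± 8.98 in CL-CM-EE-IVF (SD, n = 3). Its log2 fold changes against CL-NC of 0.44, 0.45 and 0.34 became 0.03, 0.06 and 0.03 without the R4 library of each of these 3 groups, and the first became 0.66 without CL-CM-EE R5. The lowest adjusted p over the 6 comparisons was 0.361 for extracellular vesicle biogenesis, 0.394 for prostaglandin synthesis and signalling, 0.635 for luteolysis-associated genes and 0.285 for the progesterone, oestrogen and oxytocin response. It was 0.709 for antigen presentation, 0.435 for inflammation and NF-kB targets, 0.435 for hypoxia and glycolysis, 0.538 for uterine receptivity and histotroph, 0.371 for apoptosis and survival and 0.201 for cell cycle. It was 0.125 for heat shock and unfolded protein response, 0.188 for antioxidant and metal response and 0.126 for mitochondrially encoded transcripts. Among the marker lists it was 0.632 for epithelium, 0.424 for ciliated cells, 0.424 for T and NK cells, 0.452 for B and plasma cells, 0.537 for erythroid cells and platelets and 0.163 for embryo and trophectoderm.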

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

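The settings with 3 surrogate variables, the R number block with an estimated correlation, and the list tests without 1 library were chosen after seeing the data. The number of genes past the threshold stayed at 0 in 89 checks under the other alternatives and in 52 fits without 1 library. The 89 include an adjusted p under 0.10 and a log2 fold of at least 1 in each comparison. Both only read the main fit again, where no gene had an adjusted p under 0.10, so they could give only 0. With 3 surrogate variables 12 genes passed in EE-AI against EE. Without 1 library the count ranged from 0 to 1 in EE-IVF against EE and from 0 to 1 in EE-IVF against EE-AI, with 1 without EE-IVF replicate 2. In simulated corpus luteum data, edgeR called at most 4.48% of genes changed 2-fold in the 6 comparisons, and DESeq2, run on CL-CM-EE against CL-NC, called 16.4%, with 43 false calls against 5 by edgeR. The number of genes differing between R numbers was 4872 with median-of-ratios scaling, 5046 without a filter, 6678 at an adjusted p under 0.10 and 5997 with DESeq2, within 1.5 times 5063. Taking only the titles starting with A or only those starting with X was not run, since the table has 1 column per group and number.

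The number of lists past the threshold was within 1.5 times its value in 21 alternatives and 10 fits without 1 library, and moved further in 15 alternatives and 26 fits without 1 library. With an estimated correlation, 0 lists passed in CL-CM-EE-AI against CL-NC, 1 in CL-CM-EE-IVF against CL-NC, and 0, 0 and 0 in CL-CM-EE-AI against CL-CM-EE, CL-CM-EE-IVF against CL-CM-EE and CL-CM-EE-IVF against CL-CM-EE-AI. With the R number as a block, 4 passed in CL-CM-EE against CL-NC, 5 in CL-CM-EE-AI against CL-CM-EE, 8 in CL-CM-EE-IVF against CL-CM-EE and 5 in CL-CM-EE-IVF against CL-CM-EE-AI. Pairing by R number required all 18 correlations between libraries of the same number to be over 0.1, and 15 were, so the tests do not pair the libraries. The median was 0.359 for the same number and -0.177 for different numbers, and 7 of 12 libraries correlated best with their own number in each other group. The values were centred on the group means, so positive correlations for the same number bring negative ones for different numbers. The latter are not separate evidence. All 3 same-number correlations were over 0.1 in CL-CM-EE-AI against CL-NC, CL-CM-EE-AI against CL-CM-EE and CL-CM-EE-IVF against CL-CM-EE. The relation comes from the data, not the labels, and the tests without a block leave it in the spread within groups. The printed intervals of log2 fold changes and the gene p-values come from the fits without a block, so they include that spread. A count of 0 genes in those fits therefore does not show that the groups were alike. With the block, edgeR called 0 genes in the 6 corpus luteum comparisons, and between 163 and 976 had an unadjusted p under 0.05, compared with 127 to 285 without it. With the block and the preset correlation, each list past the threshold kept its call. With this block and an estimated correlation, 0 passed in CL-CM-EE-AI against CL-NC, 0 in CL-CM-EE-IVF against CL-NC, 0 in CL-CM-EE-AI against CL-CM-EE, 0 in CL-CM-EE-IVF against CL-CM-EE and 0 in CL-CM-EE-IVF against CL-CM-EE-AI. With ranks, 7 passed in CL-CM-EE-IVF against CL-CM-EE. Without 1 library the count ranged from 1 to 9 in CL-CM-EE against CL-NC, from 4 to 10 in CL-CM-EE-AI against CL-NC and from 2 to 12 in CL-CM-EE-IVF against CL-NC. It ranged from 4 to 8 in CL-CM-EE-AI against CL-CM-EE, from 1 to 10 in CL-CM-EE-IVF against CL-CM-EE and from 0 to 11 in CL-CM-EE-IVF against CL-CM-EE-AI. The cause was not tested.

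Lists past the threshold kept their call in 93 tests under the other alternatives and 88 without 1 library, lost it in 45 and 42, and turned direction in 8 without 1 library. Under the other alternatives, every lost call came with an estimated correlation, with or without the R number block. The alternatives with the preset correlation lost none. Without 1 library, the adjusted p ranged in CL-CM-EE-AI against CL-NC from 4.79e-10 to 0.863 for cholesterol synthesis and from 0.00063 to 0.930 for endothelium. In CL-CM-EE-AI against CL-CM-EE it ranged from 6.44e-10 to 0.858 for cholesterol synthesis, from 6.54e-10 to 0.632 for oxidative phosphorylation and from 0.000235 to 0.889 for endothelium. In CL-CM-EE-IVF against CL-CM-EE-AI it ranged from 9.61e-09 to 0.750 for extracellular matrix and from 1.04e-05 to 0.751 for smooth muscle. Each of these fits left an R number missing from 1 group, and the cause of these ranges was not tested.

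Log2 fold changes of named genes kept their direction in 1415 tests under the other alternatives and 1171 without 1 library, and 41 turned. The ranges without 1 library were, in CL-CM-EE against CL-NC, -1.10 to 11.6 for ANKRD63, -0.54 to 2.78 for PTGER2, -1.73 to 0.0741 for PTGS1, -0.14 to 0.98 for PTGFR, -0.27 to 1.44 for CD9, -0.17 to 0.77 for RAB35, -0.0482 to 0.64 for TNFRSF1B and -0.0882 to 0.46 for TNFRSF1A. In CL-CM-EE-AI against CL-NC they were -0.00359 to 1.70 for PTGFR, -0.24 to 2.67 for PTGER2, -0.43 to 1.59 for STAR, -0.15 to 1.22 for IDI1, -0.00571 to 1.08 for TM7SF2, -0.12 to 0.98 for FDFT1, -1.02 to 0.0525 for FGF2, -0.89 to 0.18 for EDN1 and -0.0725 to 0.90 for LUM. In CL-CM-EE-IVF against CL-NC they were -0.81 to 2.38 for PTGER2, -0.49 to 1.48 for INSIG1, -1.31 to 0.10 for EDN1, -0.000587 to 0.75 for AGTR1 and -0.056 to 1.63 for ACTA2. In CL-CM-EE-AI against CL-CM-EE they were -11.6 to 0.64 for ANKRD63, -0.95 to 0.0429 for PTGER4, -0.0727 to 0.98 for CD63, -0.36 to 1.16 for IDI1, -0.85 to 0.14 for ERG and -0.53 to 0.10 for TIE1. In CL-CM-EE-IVF against CL-CM-EE they were -11.9 to 1.13 for ANKRD63, -1.37 to 0.0203 for CYP19A1 and -0.28 to 1.41 for ACTA2. In CL-CM-EE-IVF against CL-CM-EE-AI they were -0.0181 to 8.21 for KLF15, -1.35 to 0.46 for IFI44, -2.22 to 1.22 for PTGS2, -0.93 to 0.34 for ARF6, -0.47 to 0.0546 for VPS25, -0.87 to 0.70 for JUNB, -0.49 to 0.26 for JUN, -0.40 to 1.57 for ACTG2, -0.46 to 1.22 for ACTA2 and -0.0569 to 0.83 for MYH11. The cause was not tested.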

Other observations

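The tests on the R numbers by list, on the steroidogenesis list, on the count spikes and the definition of a spike were chosen after seeing the data. The test of other splits was not. The prediction for the smooth muscle list was written before its leave-one-out test, but leaving out libraries in list tests was itself chosen after seeing the data. The corpus luteum libraries differed more by R number than by group. With group in the edgeR model, 5063 of 18939 genes (26.7%) differed between R2, R4 and R5, with the highest mean in R2 for 1483, in R4 for 1831 and in R5 for 1749. The cholesterol synthesis list differed in 22 of 22 tested members, all highest in R4 (Fisher's exact test, adjusted p = 7.21e-12). This test takes list members as independent, while the estimated correlation between members of this list was 0.865 or more, so the p-values of these list tests do not account for it. INSIG1, a sterol-regulated protein of this list, was at 50.0 ± 10.3 CPM in R2, 313 ± 107 in R4 and 81.8 ± 19.9 in R5 (SD, n = 4). Of the interferon-stimulated genes 25 of 36 differed, 22 of them highest in R4 (adjusted p = 6.38e-07). MX1, an antiviral GTPase of that response, was at 17.4 ± 3.93, 142 ± 31.7 and 80.8 ± 5.01 CPM, and IFI6 was at 7.07 ± 0.636, 241 ± 119 and 47.0 ± 13.0 CPM.

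Hypoxia and glycolysis genes differed between R numbers in 25 of 27 members, 22 of them highest in R2 (Fisher's exact test, adjusted p = 1.32e-11). LDHA, lactate dehydrogenase A, was at 276 ± 65.5 CPM in R2, 59.0 ± 13.9 in R4 and 21.9 ± 5.15 in R5 (SD, n = 4). Matrix genes differed in 23 of 27 members, 17 highest in R2 (adjusted p = 3.46e-09), and endothelial markers in 9 of 14, 8 highest in R2 (adjusted p = 0.00969). FLT1, a receptor of vascular endothelial growth factor, was at 2050 ± 391, 461 ± 99.2 and 368 ± 68.0 CPM. Heat shock genes differed in 17 of 23 members, all 17 highest in R4 (adjusted p = 1.59e-05), and HSPA1A was at 1090 ± 109, 6500 ± 2690 and 4140 ± 1070 CPM. Luteolysis-associated genes differed in 22 of 27 members (adjusted p = 3.35e-08), smooth muscle markers in 10 of 12 (adjusted p = 0.000263) and luteal steroidogenesis in 14 of 22 (adjusted p = 0.00103). Mitochondrially encoded transcripts differed in 11 of 13 members, 9 highest in R5 (adjusted p = 9.44e-05). Permuting the R numbers within the groups allows 216 arrangements, of which 60 were drawn with a fixed seed, and 1 of them, the real one, gave as many as 5063 genes. The highest other gave 1151, so chance is an unlikely source. It is not excluded, since 1 of 60 is the smallest share possible here and the remaining arrangements were not run. The labels do not say whether the numbers mark animals, days or sequencing runs.

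The luteal steroidogenesis list was higher in CL-CM-EE-AI than in CL-NC with the preset correlation, and lost its call with an estimated one (adjusted p = 0.982 with an estimated correlation). Over the fits that each left out 1 library its adjusted p lay between 8.61e-05 and 0.793, with 0.793 without CL-CM-EE-AI R4 and 0.321 without CL-NC R2. Of its 22 members 14 differed between R numbers, 9 highest in R4 and 0 in R2. Leaving out either library thus also shifts the groups through the R numbers. Within R numbers the median log2 CPM difference was 1.09 in R4, 0.09 in R2 and 0.15 in R5. CL-CM-EE-AI R4 carrying the difference is 1 candidate explanation, which the unbalanced fits cannot decide. A larger share of luteal cells in the tissue pieces could also raise it, and would lower the markers of the other cell types. With the preset correlation, endothelial markers were lower (11 of 14 members, adjusted p = 0.0455), as that would need, and fibroblast markers were higher (8 of 10, 0.0216). Follicle cell markers were higher too (6 of 6, 0.0122). That list shares CYP19A1 with the steroidogenesis list, so it does not stand for other cell types alone. The other marker lists did not pass. Members above 0 numbered 11 of 12 for smooth muscle, 10 of 13 for macrophage, 10 of 14 for T and NK cells and 6 of 12 for ciliated cells. They numbered 4 of 9 for epithelium, 3 of 7 for erythroid cells, 2 of 7 for B and plasma cells and 2 of 6 for embryo markers. With an estimated correlation the adjusted p of endothelial, fibroblast and follicle cell markers was 0.982, 0.5 and 0.982. So a larger luteal share cannot be told apart from other sources of the difference, and an effect of the medium stays open.

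The smooth muscle list was higher in CL-CM-EE-IVF than in CL-CM-EE-AI with the preset correlation, and lost its call with an estimated one (adjusted p = 0.994 with an estimated correlation). Over the 6 fits that each left out 1 library the adjusted p lay between 1.04e-05 and 0.751, the highest without CL-CM-EE-IVF R4, when the list turned lower, and it was 0.143 without CL-CM-EE-AI R2. The fit without CL-CM-EE-IVF R4 also left R4 missing from 1 group, and 10 of 12 members differed between R numbers, 7 highest in R4. So CL-CM-EE-IVF R4 carrying the difference is a candidate explanation that this fit cannot decide. Whether that tissue piece held more smooth muscle was not tested, and an effect of the medium stays open.

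Genes with a count spike, at least 20 CPM and at least 20 times their median over the libraries (taken as at least 1 CPM), numbered 61 in the corpus luteum and 4 in the endometrium. Against a response to the medium of 1 group as the source of these spikes, 0 of the 61 were high in at least 2 libraries of 1 group and no other. With 0 genes called by edgeR between the groups this was likely beforehand, and responses of a smaller size are not covered. A response shared by the medium groups stays open: 4 genes were high in at least 2 medium groups and no CL-NC library, 3 of them in 1 R number alone, and of the genes high in 1 library 5 were in CL-NC, 23 in CL-CM-EE, 13 in CL-CM-EE-AI and 11 in CL-CM-EE-IVF. Of the 61, 85.2% were high in 1 library alone, which fell between the bounds set for an event in single libraries, so that explanation stays open, and 6 genes were high in at least 2 libraries of 1 R number and no other. The bound of 20 times decides part of this, since in 11 of the 52 genes high in 1 library the second-highest library was within 8 times of it, in 7 of them with the same R number, while counting genes at 20 times the second-highest library gave 23 in the corpus luteum and 0 in the endometrium, and at 8 times gave 47 and 1.

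Splitting the 6 libraries of a comparison into groups of 3 gives 10 splits, the real one among them, too few for a share under 0.05. Where the real count is 0, 10 of 10 splits reach it by construction, which tests nothing: this holds for genes in each of the 9 comparisons and for lists in CL-CM-EE against CL-NC. For genes, the highest other split gave 0 genes, except 1 gene in CL-CM-EE against CL-NC. For lists, the highest other split gave 11 in CL-CM-EE against CL-NC. In the other comparisons the numbers of splits include the real one, and the highest other count is in brackets. Of the 10 splits, 7 gave at least 7 lists in CL-CM-EE-AI against CL-NC (15) and 6 gave at least 7 in CL-CM-EE-IVF against CL-NC (17). In CL-CM-EE-AI against CL-CM-EE 9 gave at least 3 (12), in CL-CM-EE-IVF against CL-CM-EE 9 gave at least 4 (16), and in CL-CM-EE-IVF against CL-CM-EE-AI 9 gave at least 2 (18). The other splits with each R number on both sides gave 4, 6 and 4 lists in CL-CM-EE-AI against CL-NC and 6, 2 and 1 in CL-CM-EE-IVF against CL-NC. None reached the real 7. Elsewhere some did. The counts were 11, 3 and 1 in CL-CM-EE against CL-NC and 4, 2 and 6 in CL-CM-EE-AI against CL-CM-EE. They were 7, 4 and 1 in CL-CM-EE-IVF against CL-CM-EE and 1, 6 and 5 in CL-CM-EE-IVF against CL-CM-EE-AI. These splits, picked afterwards, are too few for a test. In all 6 comparisons the highest count came from a split that put both R5 libraries on 1 side and both R4 libraries on the other. It was tied with 2 other splits in CL-CM-EE against CL-NC, 1 of which had each R number on both sides, and with 1 other split in CL-CM-EE-AI against CL-CM-EE. In the 3 comparisons without CL-NC the highest count was several times the real one. These list tests used the preset correlation of 0.01. In CL-CM-EE-AI against CL-NC the estimated one was higher for most lists. It was 0.865 for cholesterol synthesis, 0.658 for oxidative phosphorylation, 0.446 for interferon-stimulated genes and 0.126 for luteal steroidogenesis. It was below the preset one only for the fibroblast, erythroid and embryo lists. The splits were not run with an estimated correlation. Whether a structure of the samples or the preset correlation raised the counts was therefore not tested.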
